A study of Mus musculus with 2 samples.

How the data were processed

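Total RNA was sequenced from the heart of 2 female mice at postnatal day 10, with 1 library per animal. The animals are of strain B6CASTF1/J, which per the strain name is the first-generation cross of C57BL/6J and CAST/EiJ. Per the labels, 300 ng of RNA from an animal tissue kit was used for each library and an ERCC spike-in profile for stranded libraries with reduced ribosomal RNA was given. ERCC spike-ins are synthetic RNAs added in known proportions. The labels give the 2 animals as biological replicates 1 and 2 under a single donor record, and they give no treatment, litter, batch or date that could part them.

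The deposited files hold, for each library, a gene table and 2 transcript tables, made on assembly mm10 with the GENCODE M21 annotation per the text that accompanies them. The gene table and the first transcript table were made by the authors from alignments to the transcriptome and hold the expected count of each gene or transcript, in which a read that fits several genes is shared between them. The same deposited tables hold TPM, a relative abundance corrected for length and scaled over all entries including the spike-ins, and per the file headers the first transcript table also holds the percent of the gene's TPM in each transcript. The second transcript table was made by the authors from reads and an index and holds an estimated count and TPM per transcript. Lengths, effective lengths and interval bounds are further columns per the file headers. The column headers are those that RSEM writes for the first set and those that kallisto writes for the second, and these names are used below. The tools, their versions, trimming and read length are not given in the sources used here. The deposited genome signal tracks were not used here, and reads from the 2 parental genomes were not told apart. All 55536 annotated gene entries matched the annotation by identifier.

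The deposited values have properties that bear on the measurements. Effective length differed from length by 99 nt in the RSEM tables, while the kallisto tables imply a mean fragment of 333 nt in replicate 1 and 329 nt in replicate 2. TPM therefore differ between the 2 methods, the more so the shorter the gene, and not only for genes shorter than a fragment. RSEM shares reads between copies of a gene in proportions estimated in each library separately, so a single copy of a repeated gene can move between libraries without any change in the sum over copies. Reads were assigned on the mm10 reference, which is C57BL/6J, although about equal shares of the chromosomes come from CAST/EiJ, so reads with CAST/EiJ variants could be lost in both libraries alike. The gene tables also hold 26248 entries with numeric identifiers that name no gene. They held 3.84 and 2.92 expected counts in replicates 1 and 2 and were left out of library sizes and tests, as were the spike-ins.

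Replicate 1 held 40403041 and replicate 2 held 39849597 expected counts. Shares of counts in a single library are given with exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The same holds for the standard errors of log2 ratios given as counting SE.

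With 1 group of 2 animals there is no comparison between conditions. Levels are given as the mean ± SD of the 2 libraries. A gene was counted as detected at a TPM of at least 1 in both libraries. The libraries were compared by Pearson and Spearman correlation over genes of log2(TPM + 1), by the median absolute log2 ratio of CPM (counts relative to library size) scaled by TMM factors, and by the biological coefficient of variation. That coefficient is the square root of the common dispersion from edgeR 4.0.16 in R 4.3.3, with expected counts rounded to whole numbers and an intercept-only model. Differences between the 2 libraries were tested gene by gene with an exact conditional binomial test, two-sided, on rounded expected counts. The expected share came from TMM library sizes, and Benjamini-Hochberg adjustment ran over the genes with a summed count of at least 20. A gene was called at an adjusted p under 0.05 and at least a 2-fold ratio (prior count 0.5). The edgeR quasi-likelihood test needs replicates within 2 groups and could not be fitted.

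For 26 gene pairs, the log2 ratio of TPM + 0.1 was taken within each library. A pair was read as apart when both libraries had the same sign and the mean exceeded 3 SD, because 2 libraries allow no exact p under 0.5. For 40 gene lists, the median TPM was taken in each library. The shift of a list is the median log2 ratio over members with a mean CPM of at least 1. It is given as a percentile among 10000 random lists of the same size, matched on expression in 20 bins, where at least 3 members could be used. Leading isoforms were read for 30 genes by both methods. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

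The pairs, the lists, the isoform genes and the rule for named genes were fixed before the data were examined. Named genes, not all of which are listed, are the members of the pairs, the 4 members of each list with the highest mean TPM, the 10 nuclear protein-coding genes with the highest mean TPM, the 10 noncoding genes with the most counts, and the isoform genes. Of the called genes with a mean CPM of at least 1, the 10 with the largest rise and the 10 with the largest fall in replicate 2 also come under the rule. Other list members that the text names were chosen after their values were seen, because they were called, moved with called members or stood in contrast to them. One list member, Ahsp, was not found in the annotation.

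The scripts were tested on simulated data shaped like these libraries, for the comparison of replicate 2 with replicate 1. With counting noise alone, the binomial test called 100% of 63 genes changed 3-fold and of 69 genes changed 5-fold. It called 47.1% of 68 genes changed 2-fold, which is the threshold itself, and 0 of 16284 unchanged genes. The changed genes were drawn from those with a mean count of at least 100, so recovery at fewer counts was not measured. With the measured spread between animals added and no gene changed, 49 of 16486 genes were called, so the binomial test covers counting noise only and a negative binomial count is given beside it. In the same simulation a coefficient of 0.0868 was returned as 0.0868. Of 200 random lists without a shift, simulated with counting noise alone and no variation shared between genes, 7.0% fell outside the central 95%.

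Alternatives tried were other pseudocounts, filters on low values, scaling by DESeq2 1.42.0 size factors, by total counts and by spike-in totals, other fold thresholds, the kallisto tables in place of the RSEM tables, an exact negative binomial test, posterior mean TPM, and each library alone.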

Results

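The data describe the RNA content of the heart of female B6CASTF1/J mice, a first-generation cross between laboratory strain C57BL/6J and the wild-derived strain CAST/EiJ, at postnatal day 10. There was 1 group of 2 animals, replicates 1 and 2, with 1 total RNA library each. Replicate 1 held 40403041 and replicate 2 held 39849597 expected counts. Values below are the mean ± SD over the 2 animals (n = 2) in deposited TPM unless another unit is named. The labels name no treatment or contrast, so the comparisons are those within each heart and between the 2 hearts.

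The labels give both animals as female, and the sex-linked genes were read first. Xist, the RNA that coats the inactive X chromosome, stood at 26.7 TPM in replicate 1 and 46.8 TPM in replicate 2. The Y-linked genes Kdm5d, Uty and Eif2s3y had 0 TPM in both libraries, and Ddx3y had 0 and 0.02 TPM.

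The first question is what the day 10 heart expressed. The most abundant nuclear protein-coding RNAs were those of the adult-type contractile apparatus. Myh6, the alpha myosin heavy chain, stood at 9012 ± 842 TPM (chromosome 14, 54941921 to 54966927). The ventricular light chains Myl2 and Myl3 stood at 8357 ± 250 and 4878 ± 154, cardiac actin Actc1 at 6921 ± 265, and tropomyosin Tpm1 at 4024 ± 308. Oxygen and fuel handling followed, with myoglobin (Mb) at 4484 ± 429, the fatty acid binding protein Fabp3 at 3133 ± 134, the ATP synthase subunit Atp5b at 3219 ± 223 and the sarcoplasmic reticulum calcium pump Atp2a2 at 3350 ± 204. Beta globin Hbb-bs completed these 10 genes at 3167 ± 1966, with 1777 TPM in replicate 1 and 4557 in replicate 2. These levels and their order are by RSEM and depend on the method. By kallisto, Myl2 stood at 19725 and 18388 TPM in replicates 1 and 2, above Myh6 at 8002 and 9074. Detection at 1 TPM or more in both libraries held for 12838 of 55536 annotated genes and for 11718 of 22015 protein-coding genes.

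The gene lists of working heart muscle had high levels in both hearts. All 25 sarcomere genes and all 15 calcium handling genes were detected, with list medians of 675 ± 26.2 and 149 ± 10.7 TPM. In the calcium handling list, the pump inhibitor Pln stood at 1983 ± 118, calsequestrin Casq2 at 449 ± 11.98 and the release channel Ryr2 at 330.5 ± 26.4. The gap junction gene Gja1 (264 ± 39.4) and the potassium channel subunits Kcne1 (176 ± 3.57) and Kcnip2 (59.4 ± 4.60) had the highest levels named here from the ion channel list, whose median was 14.5 ± 1.66. Of 23 cardiac transcription factors, 20 were detected, led by Mef2a at 85.3 ± 3.76, Tbx20 at 76.6 ± 19, Gata4 at 66.0 ± 11.9 and Esrra at 50.9 ± 2.26, with a list median of 18.2 ± 2.57.

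Genes of mitochondrial energy metabolism had some of the highest levels. The median of the 13 proteins encoded in the mitochondrial genome was 6576 ± 513 TPM, led by mt-Co1 at 28190 ± 1164, mt-Co3 at 12041 ± 396, mt-Cytb at 11716 ± 495 and mt-Atp6 at 10390 ± 111. Nuclear genes of oxidative phosphorylation had a median of 476 ± 26.9, with Cox4i1 at 1682 ± 77.8, Atp5a1 at 1573 ± 91.7 and Ndufa4 at 988 ± 8.11 after Atp5b. All 23 fatty acid oxidation genes were detected at a median of 341 ± 8.51, with Acaa2 at 688 ± 18.7, Hadhb at 683 ± 0.177 and the fatty acid transporter Cd36 at 637 ± 12.5. The median of the glycolysis and lactate list was 161 ± 2.67, led by Gapdh (1547 ± 157), Aldoa (1111 ± 66.1), Ldhb (743 ± 68.8) and Eno3 (723 ± 46.8). The ribosomal protein list had a median of 267 ± 8.15, with Rpl41 at 858 ± 35.98, Rplp1 at 711 ± 27.9, Rps29 at 668 ± 14.8 and Rps14 at 485.5 ± 8.65.

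Markers of dividing cells were present at lower levels. All 22 mitosis genes were detected at a median of 8.35 ± 1.12 TPM, with Cenpa at 35.9 ± 1.59, Top2a at 22.6 ± 1.59, Cdk1 at 18.4 ± 3.05 and Mki67 at 14.7 ± 1.77. All 18 DNA replication genes were detected at a median of 9.77 ± 0.707, with Pcna at 35.8 ± 0.601, Rrm2 at 19.96 ± 1.75, Mcm2 at 18.3 ± 1.94 and Rrm1 at 16.2 ± 0.636. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail and are kept in total RNA, had a median of 45.8 ± 4.75 over 68 members, led by Hist1h4h at 311 ± 16.3, Hist2h2aa2 at 268 ± 27.8, Hist1h4k at 192 ± 29.2 and Hist2h3b at 166 ± 24.4.

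The plot of list levels shows where the other cell types stood. The fibroblast list had a median of 92.8 ± 0.467 TPM, led by the collagens Col3a1 (721 ± 4.87), Col1a1 (365 ± 20.7) and Col1a2 (248 ± 12.1) and by Vim (390 ± 26.01). The endothelial median was 40.6 ± 2.36, with Cdh5 at 131 ± 1.47, Egfl7 at 123 ± 10.5, Pecam1 at 88.0 ± 2.62 and Aqp1 at 85.0 ± 8.77. The mural and smooth muscle median was 26.02 ± 0.431, with Acta2 at 227 ± 23.2, Rgs5 at 172 ± 6.58, Abcc9 at 104 ± 0.438 and Mcam at 59.8 ± 0.721. Lymphatic endothelial genes had a median of 5.40 ± 0.283, led by Prox1 at 25.01 ± 3.48, which heart muscle cells also express. Epicardial and mesothelial genes had a median of 3.99 ± 0.399, with Aldh1a2 at 17.2 ± 2.18, Msln at 16.1 ± 0.460, Upk3b at 11.9 ± 1.48 and Krt19 at 6.41 ± 0.467. The macrophage median was 3.98 ± 0.679, with the complement genes C1qa (11.3 ± 1.56), C1qb (11.1 ± 0.919) and C1qc (8.85 ± 2.35) and the receptor Csf1r (10.7 ± 1.27).

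**Figure D1:**
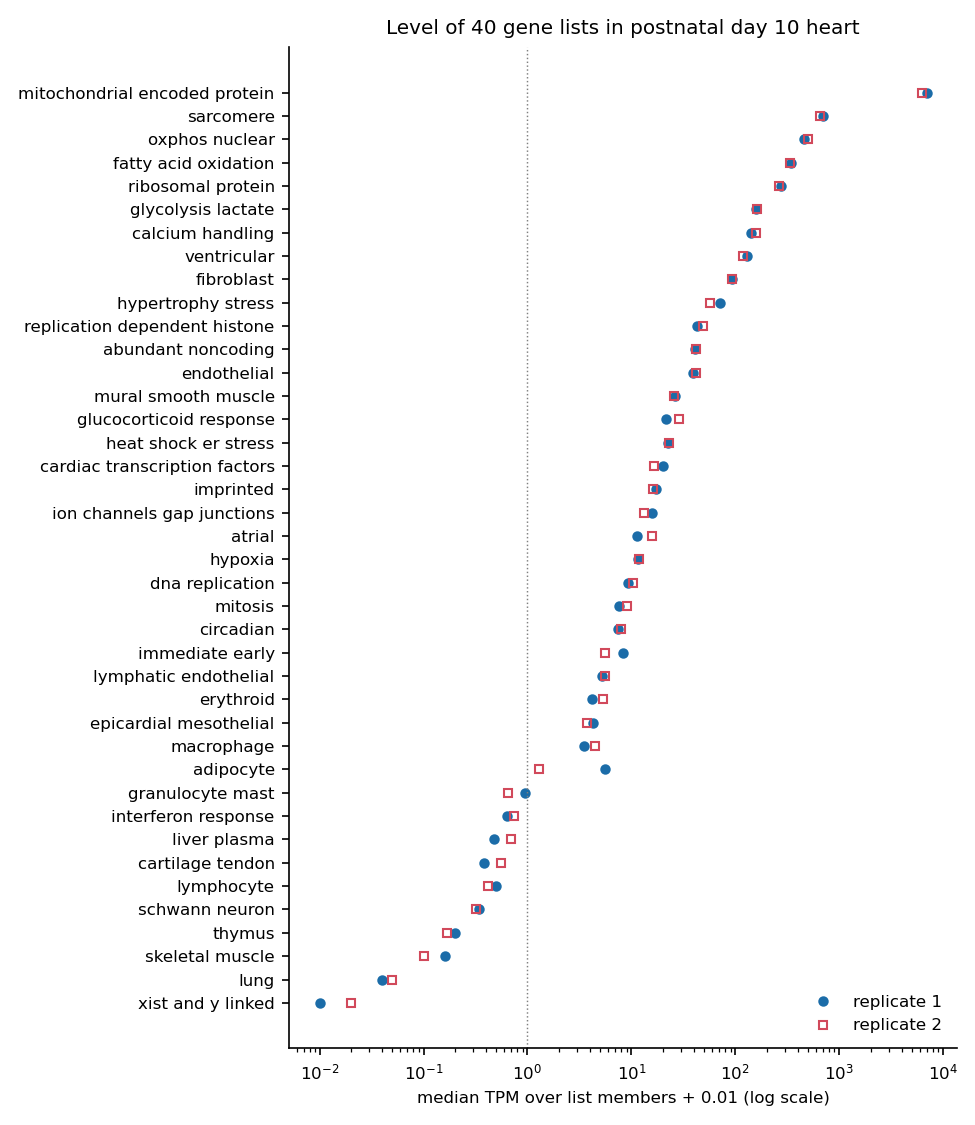
Median TPM over the members of each of 40 gene lists (log axis, 0.01 added), with a filled circle for replicate 1 and an open square for replicate 2; the dotted line marks 1 TPM. In 21 lists the median was at least 10 TPM in both libraries, and in 10 lists it was below 1 TPM in both.

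Lists for cells or organs outside the heart wall were mostly near the detection limit. The list medians were 0.448 ± 0.0530 TPM for lymphocytes, 0.175 ± 0.0212 for thymus, 0.782 ± 0.209 for granulocytes and mast cells, 0.320 ± 0.0141 for Schwann cells and neurons, 0.120 ± 0.0424 for skeletal muscle, 0.0350 ± 0.00707 for lung, 0.575 ± 0.149 for liver and plasma proteins and 0.460 ± 0.127 for cartilage and tendon. In the skeletal muscle list, Ckm stood at 1416 ± 85.7 and is also a heart gene, while Tnni2 (1.17 ± 0.594), Mylpf (0.860 ± 0.240) and Tnnt3 (0.455 ± 0.375) were close to or below 1 TPM. The lung genes Sftpc (0.395 ± 0.106) and Scgb1a1 (0.0850 ± 0.00707), the thymus gene Ccl25 (1.80 ± 0.247) and the tendon gene Scx (3.70 ± 0.919) were also below 4 TPM. The interferon response list was also low, at a median of 0.672 ± 0.0743, with Bst2 at 5.97 ± 0.742. Adipocyte genes had a median of 5.62 TPM in replicate 1 and 1.27 in replicate 2, and erythroid genes 4.14 and 5.36.

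Genes that respond to handling, hormones and time of day were read as lists too. The immediate early median was 6.89 ± 1.90 TPM, with Jund at 71.3 ± 0.615, Klf2 at 31.7 ± 5.05, Jun at 29.5 ± 4.31 and Ccn2 at 29.0 ± 2.19. Heat shock and endoplasmic reticulum stress genes had a median of 22.7 ± 0.382, led by Hspa5 at 160.5 ± 4.41, Hspb1 at 126 ± 9.71 and Hsp90b1 at 119 ± 10.5. The hypoxia list had a median of 11.8 ± 0.0778, with Vegfa at 88.7 ± 8.24, Pdk1 at 56.0 ± 5.97 and Bnip3 at 41.1 ± 6.04. The circadian median was 7.67 ± 0.339, with Per1 at 26.1 ± 1.86, Tef at 24.97 ± 5.80, Nr1d2 at 20.6 ± 2.25 and Clock at 15.5 ± 0.608. The glucocorticoid response median was 25.2 ± 4.93, and the imprinted genes had a median of 16.6 ± 0.887, led by Gnas (722 ± 24.5), Igf2 (329 ± 5.42), H19 (163 ± 13.4) and Grb10 (90.7 ± 4.49).

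The second question is how far the hearts had moved from fetal to adult isoforms, read from pairs of related genes within each library. Adult forms dominated the contractile pairs. Myh6 RNA was 11.2-fold as abundant as Myh7, the fetal beta myosin heavy chain (log2 Myh7/Myh6 −3.49 ± 0.0055), although the log2 ratio was −2.21 with kallisto and −4.77 with counts not scaled by length, so the size depends on the method and the order does not. The adult troponin Tnni3 was 10.3-fold above fetal Tnni1 (−3.36 ± 0.51), and Tnnt2 was 199-fold above the slow skeletal Tnnt1 (−7.64 ± 0.042). Skeletal actin Acta1 and smooth muscle actin Acta2 lay below Actc1 by 59.8-fold (−5.90 ± 0.43) and 30.5-fold (−4.93 ± 0.092). The skeletal calcium pump Atp2a1 and release channel Ryr1 were near 0 TPM (0.380 ± 0.0707 and 0.030), with log2 ratios to Atp2a2 and Ryr2 of −12.78 ± 0.13 and −11.31 ± 0.12.

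In most metabolic pairs the muscle-type enzyme had the higher level as well. Cpt1b, the muscle carnitine palmitoyltransferase, was 4.97-fold above the liver form Cpt1a (log2 Cpt1a/Cpt1b −2.31 ± 0.014). The glucose transporter Slc2a4 was 20.98-fold above the fetal-type Slc2a1 (−4.39 ± 0.38). Muscle forms exceeded their broadly expressed relatives in Eno3 over Eno1 (7.81-fold), Pgam2 over Pgam1 (6.75-fold), Ckm over Ckb (24.9-fold), Slc25a4 over Slc25a5 (5.64-fold), Cox6a2 over Cox6a1 (2.87-fold) and Cox8b over Cox8a (2.74-fold). Ldhb was 1.96-fold above Ldha (−0.97 ± 0.027). Cox7a2 lay below Cox7a1 at −0.30 ± 0.092, but this order was reversed with kallisto TPM (0.50) and with counts not scaled by length (0.50). Hk1 and Hk2 were not apart by more than 3 SD (0.35 ± 0.12), but with kallisto the mean was 0.81 and exceeded it.

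Pairs of growth, thyroid and pacemaker genes were read in the same way. Igf2, a fetal growth factor, was 16.1-fold above Igf1 (log2 4.01 ± 0.23), Ccnd2 was 2.47-fold above Ccnd3, and the thyroid hormone receptor Thra was 17.4-fold above Thrb (4.12 ± 0.45). The pacemaker channel Hcn4 was 5.31-fold below Hcn2 (−2.41 ± 0.27). Dio3, which inactivates thyroid hormone, had 1 and 0 counts, so its ratio to Dio2 (0.910 ± 0.226 TPM) rests on the pseudocount (−3.19 ± 0.14) and no fold is given.

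Chamber pairs favoured the ventricle, with a larger spread between the 2 hearts. Myl2 was 43.1-fold above the atrial light chain Myl7 (log2 Myl7/Myl2 −5.43 ± 0.61), and Myl3 was 34.05-fold above Myl4 (−5.09 ± 0.61). Atrial natriuretic peptide Nppa exceeded Nppb in both hearts (1.58 and 2.90), but the mean of 2.24 ± 0.93 did not exceed 3 SD. In all, 24 of 26 pairs were apart by more than 3 SD, with the first gene lower in 21 and higher in 3. No pair can reach an exact p under 0.5 with 2 animals, and the ratios with members below 1 TPM depend on the pseudocount of 0.1.

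**Figure D2:**
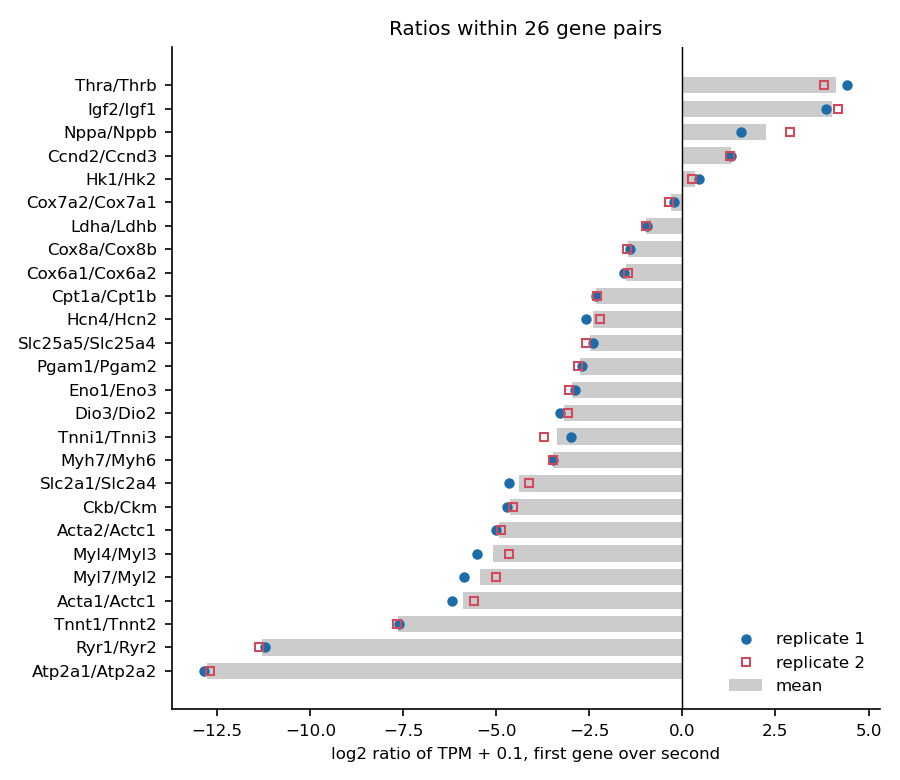
Log2 ratio of TPM + 0.1 of the first over the second gene in 26 pairs, with a filled circle for replicate 1, an open square for replicate 2 and a grey bar from 0 to their mean. Nppa/Nppb (1.58 and 2.90) differs between the 2 hearts, and Myh7/Myh6 (−3.49 and −3.48) hardly does.

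The composition of the libraries was that of total RNA from a tissue rich in mitochondria. Mitochondrial genes held 23.7% of counts in replicate 1 and 22.4% in replicate 2, or 23.1% ± 0.936 on average. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 made up 15.2% ± 0.513 and the mitochondrial mRNAs 7.89% ± 0.422. Protein-coding nuclear genes held 67.0% ± 0.884, long noncoding genes 3.40% ± 0.160, small noncoding genes 3.24% ± 0.0257, pseudogenes 2.72% ± 0.158 and ERCC spike-ins 0.558% ± 0.0239. In units of TPM, small noncoding genes held 22.04% ± 0.00583 and protein-coding genes 42.4% ± 1.20, and by kallisto counts small noncoding genes held 0.00534% ± 0.000443. The 10 genes with the most counts held 30.01% ± 0.291, and titin (Ttn) alone held 2.75% ± 0.00144. The exact 95% interval of the mitochondrial share ran from 23.70% to 23.72% in replicate 1 and from 22.37% to 22.40% in replicate 2, so the libraries differed by more than counting error.

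The noncoding genes with the most counts were mt-Rnr2, mt-Rnr1, the ribosomal RNA locus gene Gm26917 (1.99% ± 0.0357 of counts), the signal recognition particle RNAs Rn7s1 and Rn7s2 (1.21% ± 0.0545 each), Gm28661, the transcription regulator Rn7sk (0.514% ± 0.0552), Gm10925, Malat1 (0.427% ± 0.0604) and Gm42418 (0.413% ± 0.186). Gm28661 and Gm10925 are annotated as pseudogenes on chromosome 1, and Gm10925 had 194659 and 163371 counts by RSEM but 1.03 and 0.071 by kallisto, so its level is not known. Whether these 2 entries share sequence with mitochondrial genes was not tested, so the pseudogene and mitochondrial shares may not be fully separate. Among the mitochondrial mRNAs, mt-Co2 stood at 671 and 621 TPM by RSEM and at 4430 and 3141 by kallisto in replicates 1 and 2. Rn7s1 and Rn7s2 received identical counts in each library, so their reads were divided evenly and the single levels are not known. The abundant noncoding list had a median of 41.3 ± 0.371 TPM, in which Rpph1, the RNA of ribonuclease P, stood at 5323 ± 428. By kallisto, Rn7sk had 0 counts in both libraries, so the levels of some of these noncoding genes depend on the method.

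The third question is how alike the 2 hearts were. Over 25568 genes, log2(TPM + 1) correlated between the libraries with a Pearson r of 0.994 and TPM with a Spearman rho of 0.951, where genes are not independent replicates. The median absolute log2 ratio was 0.098 over the 12838 detected genes, 97.4% of which lay within 1.5-fold, and 85 lay over 2-fold apart. The biological coefficient of variation was 8.68% over 15907 genes.

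Lists of blood, atrial and hormone-responsive genes were higher in replicate 2, and adipocyte genes were lower. In the erythroid list, 7 of 10 tested genes were called higher in replicate 2, adjusted over the list alone as over all genes. Hbb-bs was 2.59-fold, Hba-a1 2.32-fold, Hba-a2 2.51-fold and Hbb-bt 2.67-fold higher, and Alas2, the first enzyme of heme synthesis in red cells, was 2.34-fold higher (chosen after its value was seen). The embryonic globins Hbb-y, Hba-x and Hbb-bh1 had 0 TPM in both. In the adipocyte list, 5 of 9 tested genes were called lower in replicate 2, adjusted over the list alone as over all genes: Ucp1, the uncoupling protein of brown fat, by 6.45-fold, Plin1 by 7.12-fold, Adipoq by 6.62-fold, Cidec by 5.32-fold and Cfd by 4.36-fold (the last 3 chosen after their values were seen). Fabp4 (445 and 476 TPM) and Plin4 (32.6 and 34.6 TPM), the most abundant members, did not differ by 2-fold, nor did Pparg (5.62 and 5.04 TPM).

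In the atrial list, 10 of 11 members had higher values in replicate 2, with 1 call (Bmp10, 2.17-fold), adjusted over the list alone as over all genes. Nppa stood at 247 and 463 TPM, Myl7 at 146 and 256, Myl4 at 104 and 197, Kcnj3 at 6.18 and 13.3 and Sln at 9.12 and 15.8, where Bmp10, Kcnj3 and Sln were chosen after their values were seen. The ventricular list had the opposite sign, with a median log2 ratio of −0.091 and 0 calls, adjusted over the list alone as over all genes. In the glucocorticoid response list, 4 of 10 genes were called higher, adjusted over the list alone as over all genes: Zbtb16 by 3.97-fold, Mt2 by 3.62-fold, Fkbp5 by 2.26-fold and Mt1 by 2.26-fold (Mt2 and Fkbp5 chosen after their values were seen). Tsc22d3 stood at 55.8 and 78.1 TPM, Sgk1 at 26.8 and 29.96, and Pdk4 at 389 and 335.

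**Figure D3:**
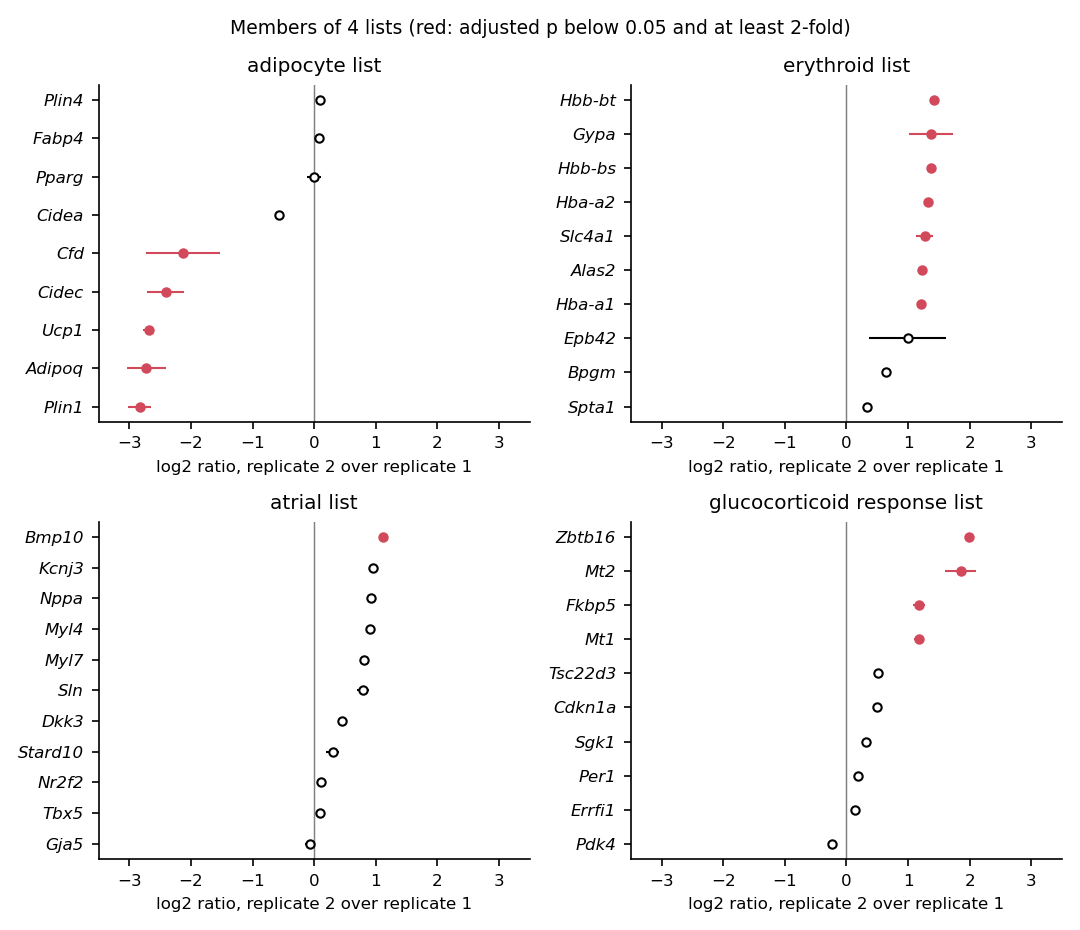
Log2 ratio of replicate 2 over replicate 1 for the tested members of the adipocyte, erythroid, atrial and glucocorticoid response lists, with bars of 1 counting SE; red marks genes called at an adjusted p under 0.05 and at least 2-fold. Called genes number 5, 7, 1 and 4.

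Of 36 lists with a percentile, 20 lay outside the central 95% of matched random lists, 14 high and 6 low in replicate 2. If the members of a list varied independently, 1.8 would lie outside by chance. The high ones had median log2 ratios of 1.27 (erythroid), 0.80 (atrial), 0.64 (liver and plasma), 0.51 (glucocorticoid response), 0.32 (interferon response), 0.30 (macrophage), 0.27 (mitosis), 0.23 (hypoxia), 0.19 (histones), 0.16 (glycolysis and lactate) and 0.10 (endothelial, immediate early and oxidative phosphorylation), and 0.087 for the sarcomere. The liver and plasma median rests on 3 of 10 members, of which 1 was lower in replicate 2. The interferon response median rests on 6 of 14, of which 2 were lower. The low ones had −1.49 (adipocyte), −0.18 (epicardial and mesothelial), −0.13 (imprinted), −0.12 (abundant noncoding), −0.12 (mitochondrially encoded proteins) and −0.091 (ventricular). Mitosis genes had higher values in replicate 2 for 21 of 22 members and histone genes for 58 of 63, while 0 of 13 mitochondrially encoded mRNAs did, with no calls in these 3 lists, adjusted over the list alone as over all genes. Scaling on the ERCC spike-ins lowers the log2 ratio of every gene by about 0.105, which turns the sign of the sarcomere (−0.018), oxidative phosphorylation (−0.0033), endothelial (−0.00061) and immediate early (−0.00075) medians and of no other list outside the central 95%. In the simulation without shifts 7.0% of 200 lists fell outside, which is too few lists to tell whether the percentiles are too narrow for counting noise alone. That simulation held no variation shared between list members, so how many lists any 2 hearts would place outside is not known.

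**Figure D4:**
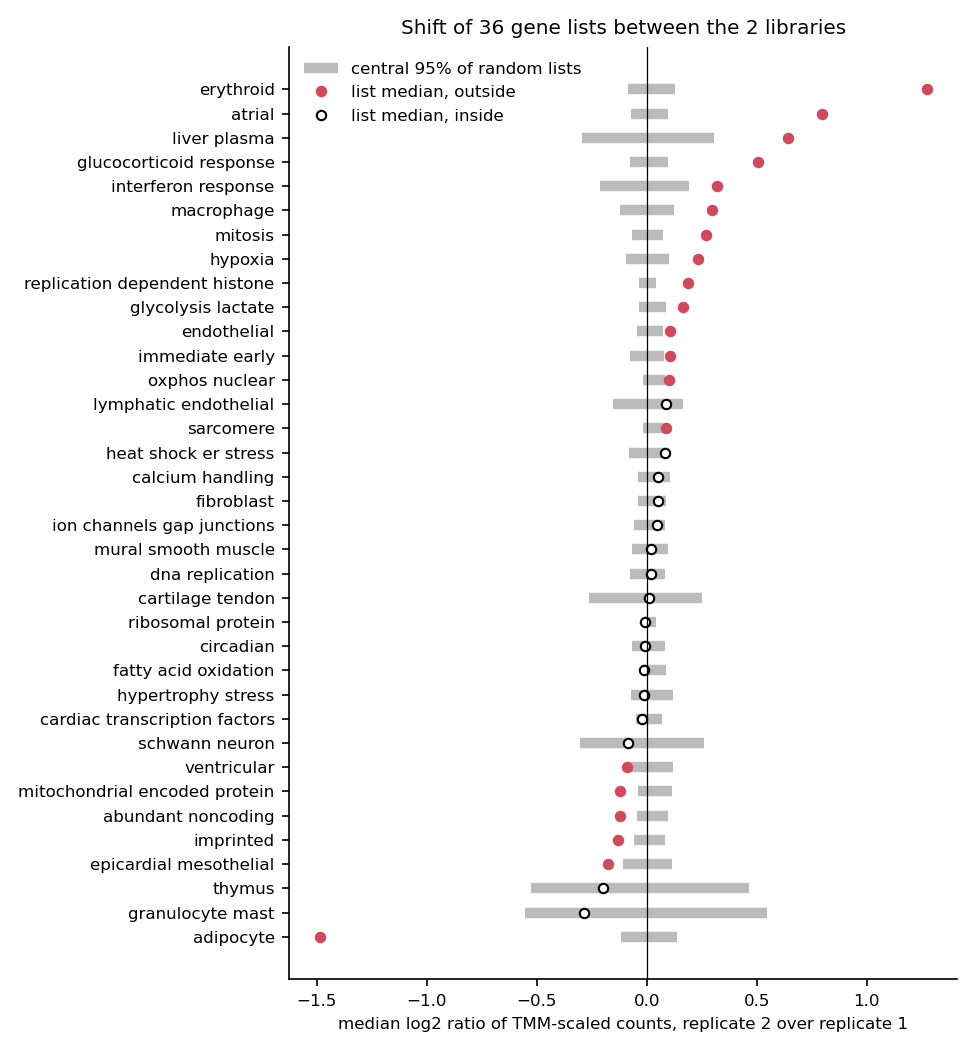
Median log2 ratio of replicate 2 over replicate 1 for 36 gene lists, with a grey bar for the central 95% of 10000 random lists of like expression; filled red circles lie outside the bar and open circles inside. The erythroid (1.27) and adipocyte (−1.49) lists lie farthest from 0, and with spike-in scaling the sarcomere, oxidative phosphorylation, endothelial and immediate early medians change sign.

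The 16 other lists lay inside the central 95% without adjustment. Their median log2 ratios were 0.088 (lymphatic endothelial), 0.081 (heat shock), 0.052 (calcium handling), 0.051 (fibroblast), 0.049 (ion channels), 0.021 (mural), 0.020 (DNA replication), 0.010 (cartilage and tendon), −0.0061 (ribosomal proteins), −0.0075 (circadian), −0.012 (fatty acid oxidation), −0.014 (hypertrophy and stress), −0.023 (cardiac transcription factors), −0.087 (Schwann cells and neurons), −0.20 (thymus) and −0.29 (granulocytes and mast cells), and the positive ones turn negative with spike-in scaling. Members were also called in lists with a flat median, among them the stretch-responsive hypertrophy gene Ankrd1, which was 2.37-fold lower in replicate 2. Nr4a1 (2.54-fold) and Nr4a3 (3.12-fold) were lower in the immediate early list, whose median TPM was 8.24 in replicate 1 and 5.55 in replicate 2 although its median log2 ratio was 0.10 (both, like Nnat below, chosen after their values were seen). Rag1, Nnat, S100a8 and Alb were the calls in 4 further lists, with 1 each, adjusted over the list alone as over all genes.

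Across all 16517 genes tested, 212 were called, 101 higher and 111 lower in replicate 2, of which 101 had a mean CPM of at least 1. With spike-in scaling the split was 85 higher and 157 lower. Among the called genes with a mean CPM of at least 1, the largest rise called by both methods was that of Lars2 (ENSMUSG00000035202.8, chromosome 9), the mitochondrial leucyl-tRNA synthetase, with 2374 counts in replicate 1 and 25712 in replicate 2 (11.1-fold, log2 3.47 ± 0.031 counting SE). Zbtb16, Alb, the noncoding gene AC160336.1 (4.09-fold), Mrap2 (14 and 66 counts) and Fam220a (121 and 464 counts) were also higher by both methods. Lower by both methods were Plin1 and Car3, a carbonic anhydrase of muscle and fat (915 and 126 counts).

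The other genes named below, apart from Chtf8, were called by RSEM counts alone, and several are pseudogenes or overlapping entries. The 2 U3 snoRNA entries named Rnu3a share 1 place on chromosome 10 (40258467 to 40258680 and to 40258679) and mirrored each other. ENSMUSG00000065870.2 had 372 and 0 counts and ENSMUSG00000106147.1 had 1.98 and 268, so they cannot be read as 2 genes that changed. Prn (274 and 0 counts), Gm13394 (184 and 0), Gm6361 (122 and 0), Gm20388 (108 and 0.17) and Rpl7a-ps11 (107 and 0) were lower in replicate 2, and Gm6565 (0 and 96.9), Gm14760 (44.6 and 259) and Gm12070 (36.4 and 140) were higher. By kallisto, Prn had 1188 and 1000 counts, Gm20388 681 and 683 and Gm14760 29.4 and 28.1, while Rnu3a, Gm6361 and Gm6565 had 0 in both libraries. Chtf8 (ENSMUSG00000117748.1) had 313 and 7.36 counts by RSEM and 2.86 and 80.4 by kallisto, so its direction was reversed. The binomial test covers counting noise only: an exact negative binomial test with the measured spread called 128 genes, and 108 were called by both methods in the same direction (an alternative added after the data were examined).

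The last comparison is between the 2 quantification methods on the same reads. Gene-level TPM by RSEM and kallisto correlated with a Spearman rho of 0.884 in replicate 1 and 0.887 in replicate 2 over 55450 genes. Of genes with at least 1 TPM by either method, 1619 in replicate 1 and 1516 in replicate 2 differed by 2-fold or more. The count ratio followed gene length: the median kallisto count was 0 times the RSEM count in genes under 300 nt, 0.0729 times between 300 and 400 nt, 0.753 times between 400 and 600 nt and 1.08 times between 2000 and 5000 nt in replicate 1. For the light chain Myl2 the TPM was 8533 by RSEM and 19725 by kallisto in replicate 1, although the counts were close (130116 and 135147). For the spike-ins with at least 50 counts, 34 in number, log2 counts correlated between the libraries with a Pearson r of 0.999.

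**Figure D5:**
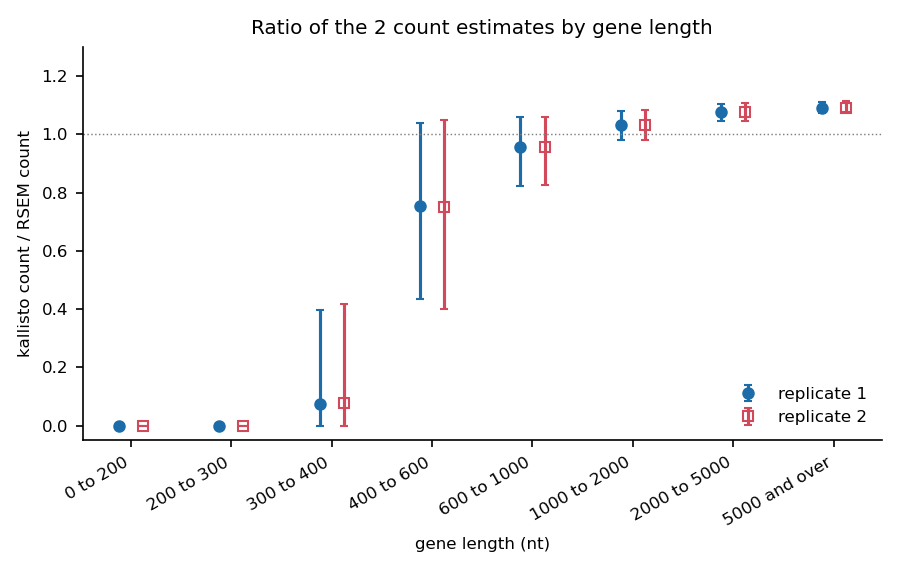
Median ratio of the kallisto to the RSEM count by gene length for genes with at least 100 counts, with a filled circle for replicate 1, an open square for replicate 2 and bars for the quartiles. The median is 0 below 300 nt and 1.09 at 5000 nt and over.

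Leading isoforms of 30 genes with known splicing in heart were mostly shared between methods. RSEM and kallisto named the same leading transcript in 24 genes and differed in Tnnt2, Pkm, Fn1, Tjp1, Lmna and Slc8a1. Tpm1-205 held 96.3% ± 0.263 of Tpm1 TPM by RSEM and 70.7% ± 0.207 by kallisto, and Slc25a3-206 held 89.2% ± 0.987 and 73.4% ± 0.908. Ryr2-201 (78.2% ± 2.17 and 79.1% ± 2.70), Atp2a2-202 (75.7% ± 0.850 and 82.3% ± 0.928), Tpm2-203 (81.7% ± 4.66 and 83.5% ± 3.60) and Fxr1-201 (63.2% ± 2.04 and 62.2% ± 3.25) led by both. Titin was divided, with 38.6% ± 1.12 in Ttn-201 by RSEM and 40.2% ± 1.79 by kallisto. For Tnnt2, RSEM gave 47.8% ± 0.625 to Tnnt2-211, to which kallisto gave almost none, and kallisto gave 53.8% ± 3.20 to Tnnt2-209. The transcript shares differed by a median of 1.78 points between the animals and 8.53 points between the methods.

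In other isoform genes, the leading shares by RSEM were 67.4% ± 8.00 for Fhl1-201, 68.6% ± 4.33 for Myocd-203, 61.7% ± 0.152 for Mef2a-208, 58.4% ± 1.33 for Mef2d-201, 56.6% ± 0.733 for Ldb3-203, 52.6% ± 1.69 for Camk2d-202, 49.8% ± 8.20 for Bin1-205, 49.3% ± 4.12 for Actn1-201, 45.8% ± 0.411 for Pdlim5-205, 41.3% ± 5.72 for Speg-201, 41.2% ± 3.29 for Cacna1c-218, 33.8% ± 0.724 for Tead1-201, 27.5% ± 0.769 for Nebl-202, 24.99% ± 2.29 for Mef2c-212 and 24.1% ± 2.01 for Mbnl1-201. Of the 30 leading transcripts, 29 were annotated as protein-coding, and Cacna1c-218 as a processed transcript. The leading transcript was the same in both animals in 28 of 30 genes by RSEM and in 29 by kallisto.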

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

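The count of genes called by both quantification methods, the adjustment for GC content and length, and the shares without ribosomal RNA locus genes and Lars2 were chosen after seeing the data; the other alternatives were chosen before the data were examined. Of 790 alternative values, 646 stayed the same in direction and side of the threshold or within the spread, 121 moved, 13 lost a call, 5 gained one and 5 were reversed. Among the summary results, 36 of 53 stayed within these limits, which for a count is 1.5 times. Genes detected ran from 8922 at a TPM of 5 to 17964 at a TPM of 0.1, with 15991 at 10 counts and 13194 by kallisto. The number of pairs apart was 24 under each alternative with both libraries, and lists outside the central 95% numbered 19 to 22. Genes with the same leading isoform by both methods numbered 24 without replicate 1 and 22 without replicate 2.

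The Pearson correlation of 0.994 became 0.982 with a pseudocount of 0.1, 0.996 with a pseudocount of 5, 0.992 for genes with at least 1 TPM in both libraries, 0.997 with CPM and 0.994 with kallisto. The 212 genes called became 90 with a summed count of at least 100, 456 with a 1.5-fold threshold, 2867 with no fold threshold, 128 with the negative binomial test and 108 when both methods had to call them in the same direction. The first 4 follow from fewer genes tested, a lower fold or no fold, and a wider assumed spread, and the last from a second condition. With DESeq2 size factors or total counts 214 were called, and kallisto called 224, of which 111 were shared. The coefficient of variation was 0.092 without a filter and 0.092 with kallisto. The median absolute log2 ratio was 0.13 with spike-in scaling, 0.076 at 10 TPM or more and 0.15 without a filter. The mitochondrial share was 26.02% of TPM, and the agreement between methods was 0.893 for genes with at least 1 TPM by either; the cause was not tested.

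Spike-in scaling changed the sign of 12 list medians, 4 of them outside the central 95%, as given with the list results; percentiles were not taken with that scaling. The 5 reversed values came with kallisto or without length scaling. The log2 ratio by kallisto was 0.045 for Gm20388, 4.56 for Chtf8 and −0.0097 for Gm14760, and that of Cox7a2/Cox7a1 was 0.50 with kallisto and 0.50 without length scaling; the cause was not tested. The sarcomere shift left the outer range with kallisto, where its size was alike (0.088, percentile 97.05 against 97.64), and after the adjustment (0.032), and the interferon shift without the CPM filter. Outside it came fatty acid oxidation (−0.070, percentile 0.225) and ribosomal proteins (−0.029, percentile 1.76) after the adjustment, and the thymus (−0.62) and hypertrophy (−0.16) lists without the CPM filter. Depth limits genes of few counts: 90 of the 212 called genes had a summed count of at least 100 and were called among those alone.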

Other observations

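The tests on Lars2 and on the 2 quantification methods, the reading of chromosome X and the choice of the genes named in the next paragraph were made only after the results were seen. The further lists of adipose, erythroid, atrial, myelin and blood leukocyte genes were also written after the patterns were seen, but before their own values were.

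Some called genes outside the fixed lists are named here one by one, picked for their known roles after their values were seen and with no test of them as a group. Among those lower in replicate 2, Pck1, which feeds glycerol synthesis in fat, was 5.68-fold lower (772 and 132 counts), Acvr1c 6.01-fold, Otop1, a brown fat gene, 4.16-fold, Angptl4, an inhibitor of lipoprotein lipase, 2.36-fold, Cdo1 2.32-fold and the desaturase Scd4 2.03-fold. Higher in replicate 2 were the platelet gene Ppbp (2.63-fold), Tent5c (2.16-fold), the mitochondrial iron importer Slc25a37 (2.06-fold), Hif3a (2.14-fold) and Timp4 (2.22-fold). In the further lists, 2 of 22 adipose genes, 0 of 21 erythroid genes and 0 of 13 atrial genes were called, where the numbers of genes include members with too few counts to test.

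Genes on chromosome X had slightly lower values in replicate 2 relative to the autosomes. The median log2 ratio was −0.038 over 455 genes, of which 42.2% were higher in replicate 2, while autosome medians ran from −0.010 (chromosome 3) to 0.015 (chromosome 5). Xist stood at 26.7 and 46.8 TPM in the same libraries. With GC content, length and level regressed out, the chromosome X median was −0.026, at percentile 0.21 of matched random lists against 0 without the adjustment.

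The adipocyte, erythroid and atrial lists lay farthest from 0 between the libraries. The tables argue against a trend with GC content or length as the whole cause, since 0 of the 3 lists fell inside the central 95% once GC content, length and level were regressed out. Less adipose tissue in replicate 2 is a candidate explanation for the first list but is not decided either. The 16 further adipose genes had a median log2 ratio of −0.099 ± 0.085 (bootstrap SD), past the random bound of −0.066 by less than that SD. They lay at percentile 0.29 of matched random lists and 2.49 after the adjustment, with 5 of the 16 higher in replicate 2. Their median is also far smaller in size than the −1.49 of the adipocyte list. More atrial tissue may account for the atrial list, as 9 further atrial genes had a median of 0.28 ± 0.12 at percentile 100, led in level by Pam at 256 and 257 TPM, which did not move. More blood stays undecided: 9 further erythroid genes had a median of 0.12 ± 0.075 at percentile 97.0, short of the bound of 0.13 stated beforehand by less than its SD (a margin required only after the value was seen), and 98.6 after the adjustment, and Ucp2, Tfrc, Ank1 and Fech among them have high levels in this heart (297, 131, 88.4 and 64.9 TPM). The further myelin list (percentile 59.9, 4 members) and the blood leukocyte list (86.2, 3 members) stayed inside. Beyond tissue content, no biological explanation was tested, since both animals form 1 group.

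Lars2 and some transcripts of the ribosomal RNA locus were higher in replicate 2, with Gm42418 at 113632 and 216725 counts and CT010467.1 at 59 and 119, while Gm26917, the most abundant of the 3 searched, hardly moved (795529 and 804723). A rise of the Lars2 transcripts in general is argued against by Lars2-201, which had the most counts in replicate 1 and moved by at most 0.061 on the log2 scale by either method, while Lars2-209 had 670 and 23985 counts. Reads of ribosomal RNA assigned to Lars2 may contribute, because 1 gene, Lars2, held a conserved stretch of 16 nt of large-subunit ribosomal RNA, in 2 of its 9 transcripts. No stretch of 31 or 25 nt was shared by Lars2 with the 3 locus transcripts searched (0 each). None of these 3 holds the 16 nt either, so this cannot decide on reads from that part of ribosomal RNA. Against such reads, Lars2-201 holds the same 16 nt, and kallisto also placed 547 and 9927 counts on Lars2-205, which does not. A switch from other Lars2 transcripts to Lars2-209 is argued against too. The transcripts other than Lars2-209 together had 1704 and 1727 counts by RSEM, and 2891 and 12303 by kallisto, so they did not fall. A rise of Lars2-209 alone stays open, as do AC160336.1 and Gm20186, and no other biological explanation was tested.

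Kallisto counts lay far below RSEM counts for short genes. Reads shared between copies are argued against as the whole cause, since the 6 genes under 300 nt that share no 31-nt stretch with another gene had a median count ratio of 0, although 66 of 72 do share one. Fragments longer than the transcript that kallisto drops may account for it: over 34 spike-ins the count ratio followed the share of positions that a mean fragment allows, with a Spearman rho of 0.758 and 0.730 in replicates 1 and 2. The spike-ins ran from 505 to 1994 nt and the rho with length itself was equal, so this cannot separate the overhang from another length trend, and the limit for this test was set near the value found. No biological explanation was tested.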
